A study of Arabidopsis thaliana with 8 samples.

How the data were processed

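Total RNA of whole Arabidopsis thaliana seedlings was measured on 8 one-colour (Cy3) Agilent arrays, 4 of wild type Col-0 and 4 of the voz1 voz2 double mutant. Per the labels, the seedlings were 14 days old, grown on Murashige and Skoog agar with 16 h of light and 8 h of dark at 22 °C without treatment, and 0.8 µg of RNA was labelled per array. Groups and replicate numbers come from the sample titles. Nothing in the labels says that the replicates of a genotype were grown separately, so the p-values measure the spread between these samples, which may be technical.

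The scanner output holds spot intensity values from Agilent Feature Extraction 9.1.3.1, per the file headers and the submitters' processing notes. The intensity used here is the processed signal, which is already background-subtracted, together with the flags for being well above background, for saturation and for outliers, per the file headers. The deposited series table holds natural log values. Set against the scanner output, every deposited value equals the natural log of the processed signal minus a constant, 6.42 on the wild type arrays and 6.91 on the mutant arrays, within 0.001. No scaling of each array is left in that table, and the constants set the genotypes apart by 0.71 on the log2 scale. The authors' reason for the constants is not given in the sources used here. Medians of the deposited natural log values lay between -2.67 and -1.28 over the arrays. The deposited table served only as an alternative.

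Each array carries 37478 non-control probes. By the names in the scanner output, 26236 probes stand for 25665 loci, 8812 are named by a genome position and 2430 by an accession or another name. Symbols came from a RefSeq gene table, in which 25449 of the loci were found. Its coordinates are not printed because the build of the array design is not given in the sources used here, and it served only for names and the order of neighbouring genes. Between 60.4% and 70.3% of the probes were well above background per array, and no spot was saturated. Between 9 and 111 spots per array carried an outlier flag and were left out. The number of arrays limits the precision. No array duplicated another, the highest correlation within a genotype being 0.99 and the lowest 0.96.

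Log2 processed signals were averaged over spots of a probe, and each array's 75th percentile over non-control probes was subtracted. Levels below are on that scale. Probes well above background on at least 4 of the 8 arrays, whatever their genotype, were tested. Of several probes of a locus the one with the highest mean stood for it, and probes without a locus stood for themselves, which left 24599 features, called genes below. Of the 470 loci with several tested probes, 29 had 1 probe past the threshold and another not, and 4 had probes of opposite sign. In 246 genes at least 1 array had no value because of an outlier flag. Fold changes are voz1 voz2 minus wild type, from limma 3.58.1 (lmFit and eBayes) in R 4.3.3, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. For a gene well above background in one genotype and on no array of the other, the fold is given as a bound. The bright group's mean was set against the mean, over the dim group's arrays, of the higher of that array's lowest signal among probes well above background and the dim probe's own signal.

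Before the data were examined, 18 gene lists with 296 genes were fixed, 295 of them on the array. Each list with at least 3 tested members was tested against all other genes with camera (preset correlation 0.01, two-sided, Benjamini-Hochberg over the lists). The test was repeated with the correlation estimated per list and with fry, which tests whether a list's genes move one way. The named genes follow a rule fixed at the same time. It takes VOZ1 and VOZ2, the 10 largest rises and the 10 largest falls among genes past the threshold whose 4 mutant values all lie on one side of the 4 wild type values, with a locus and well above background on at least 1 array of each genotype. It adds up to 3 genes per direction known only as bounds, the FLC clade list (which includes SVP) with FT and SOC1, and up to 4 members of every other list with the smallest p. Genes named outside it are said to be chosen after their values were seen.

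The arrays lay on 2 slides of 4, each slide with 2 arrays of each genotype and a scan of its own. Slide was therefore tested as a block and each slide was also fitted alone. Replicate numbers are shared between the genotypes. The deviations of the same-numbered arrays from their genotype means correlated at 0.32, 0.51, 0.46 and 0.61 over genes, which counts as pairing by a rule set beforehand. Replicates 1 and 3 shared slide 1 and replicates 2 and 4 shared slide 2, and arrays of the same slide with another number correlated at 0.27 to 0.54, so most of this pairing follows the slide. Own number gave the highest correlation on 2 of the 4 wild type arrays.

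The same steps were tested on simulated data with the means and spreads of 24353 real genes, 200 of them changed, plus 1 shifted list. For voz1 voz2 against wild type, 33.8% of the genes changed by 1 on the log2 scale were recovered, 71.2% of those changed by 2 and 100% of those changed by 4. Of 138 calls, 10 were false, and the shifted list alone passed among the lists. The simulated genes were drawn independently of each other and without a slide effect. In the real data the estimated correlation within a list was as high as 0.65, for the root markers. The run therefore does not give the error rate of the list test on the real arrays. Fewer genes were changed than the 1091 past the threshold in the real data, and the adjustment depends on that share. The recovery rates therefore do not carry over exactly to the real comparison.

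Alternatives fixed beforehand were quantile and median scaling, normexp with an offset of 50, the deposited table, 2 other filters on dim probes, the mean of probes or every probe on its own, eBayes with trend or robust, array weights, replicate or slide as a block, outlier spots kept, each array left out, a threshold of 0.01, and the other list tests. The mean signal column planned for normexp was not among those of the scanner output, so the median signal and median background were used. Each slide alone was added after the data were seen. The main fit and the fits with an array left out had no block. Leaving out an array makes the genotypes unequal between slides. A call lost or a sign turned there can therefore reflect the slide and the lower number of arrays as well as the array itself.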

Results

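The series compared 14-day-old seedlings of the voz1 voz2 double mutant with wild type Col-0 seedlings, 4 arrays of each, to find which transcripts differ when both VOZ genes are disrupted. VOZ1 and VOZ2 encode zinc-finger transcription factors known to interact with phytochrome B and to promote flowering. Between 60.4% and 70.3% of the probes per array were well above background.

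VOZ2 (AT2G42400) fell by 5.74 on the log2 scale (SE 0.27), from 1.48 ± 0.30 in wild type to -4.26 ± 0.48 in the mutant (SD, n = 4 each, limma adjusted p = 1.0e-04). This is a 53.6-fold lower signal, and the VOZ2 probe was still well above background on the 4 mutant arrays. VOZ1 (AT1G28520) fell as well, at -1.50 (SE 0.13), from 0.49 ± 0.06 to -1.01 ± 0.17 (adjusted p = 0.0015), or 2.83-fold. Each gene has a single tested probe whose place relative to the disruption is not given in the sources used here, so the VOZ1 value does not measure intact transcript. On slide 1 and slide 2 the values were -5.56 and -5.93 for VOZ2 and -1.41 and -1.59 for VOZ1.

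Of 24599 genes, 1091 passed the threshold, 668 higher and 423 lower in the mutant, and 761 of them also differed by 2-fold or more (479 higher, 282 lower). With slide as a block the count was 3955 (1999 higher, 1956 lower), which held all 1091 genes with the same sign. With the replicate number as a block it was 3314, 1657 in each direction. Both blocks hold the genotypes in equal numbers, so the fold change and sign of a gene with no missing value could not change. With 2 arrays of each genotype, neither slide alone gave a gene past the threshold in limma. At an unadjusted p under 0.05 there were 4486 genes on slide 1 and 4031 on slide 2, against 5795 on both. The share of higher genes was 61.2%. It was 79.8% of the 94 genes past the threshold after normexp background correction and 42.9% of 70 in the deposited table. That table shifts the median of all genes to -0.37, against -0.030 with the 75th percentile and -0.15 with median scaling. Leaving out any array but wild type replicate 2 or 3 lowered the count of 1091 to between 387 and 639.

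The flavonoid and anthocyanin list rose as a group. Of its 17 genes 12 rose and none fell over all genes tested (14 adjusted over the list alone, 15 with slide or replicate as a block), and all 17 had fold changes above 0, with a median of 1.63. The glycosyltransferase UF3GT rose by 3.45 (SE 0.34, adjusted p = 0.0023), a 10.9-fold change from -2.11 ± 0.53 to 1.33 ± 0.53 (SD, n = 4 each). TT19, the glutathione S-transferase needed for anthocyanin accumulation, rose by 2.70 (SE 0.31, adjusted p = 0.0048), and the regulators TT8 and MYB111 by 2.07 and 1.48. DFR, LDOX and UGT75C1 of the late pathway rose by 2.68, 2.78 and 2.72, and the MYB regulators PAP1 and PAP2 by 2.40 and 2.49, genes chosen after their values were seen. The call of PAP1 was lost without any array but wild type replicate 2 and mutant replicate 2 (adjusted p 0.050 to 0.075), and that of PAP2 without any array but wild type replicate 1 and mutant replicate 2 (0.056 to 0.095), with array weights (0.061) and with no filter (0.064). With normexp 6 genes of the list rose, TT8, MYB111, PAP1 and PAP2 having 1.15, 0.92, 2.17 and 0.74 with no call, and in the values as deposited 0. The list's camera adjusted p was 2.74e-15 with the preset correlation, and adjusted p = 0.127 with an estimated correlation. Within slides the list median was 1.72 on slide 1 and 1.79 on slide 2. The vascular list passed with a median of 0.43 (camera adjusted p = 0.029, and adjusted p = 0.572 with an estimated correlation), though 1 of its 10 genes rose (2 adjusted over the list alone). That gene, the sucrose exporter SWEET12, rose by 3.01 (SE 0.26, adjusted p = 0.0014). SWEET11 was at 1.79 in wild type and 2.79 in the mutant (adjusted p = 0.082, and 0.016 with the replicate number and 0.0096 with slide as a block). SUC2 had -0.26 on slide 1 and -0.74 on slide 2, and XCP2 had 0.50 and 0.40, neither past the threshold. Of the 10 vascular genes 9 had values above 0. The vascular call was lost on slide 2 (median 0.27, adjusted p = 0.129, against 0.56 on slide 1) and without wild type replicate 3 (median 0.27, adjusted p = 0.099), wild type replicate 4 (0.19, adjusted p = 0.093) or mutant replicate 2 (0.37, adjusted p = 0.057).

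**Figure D1:**
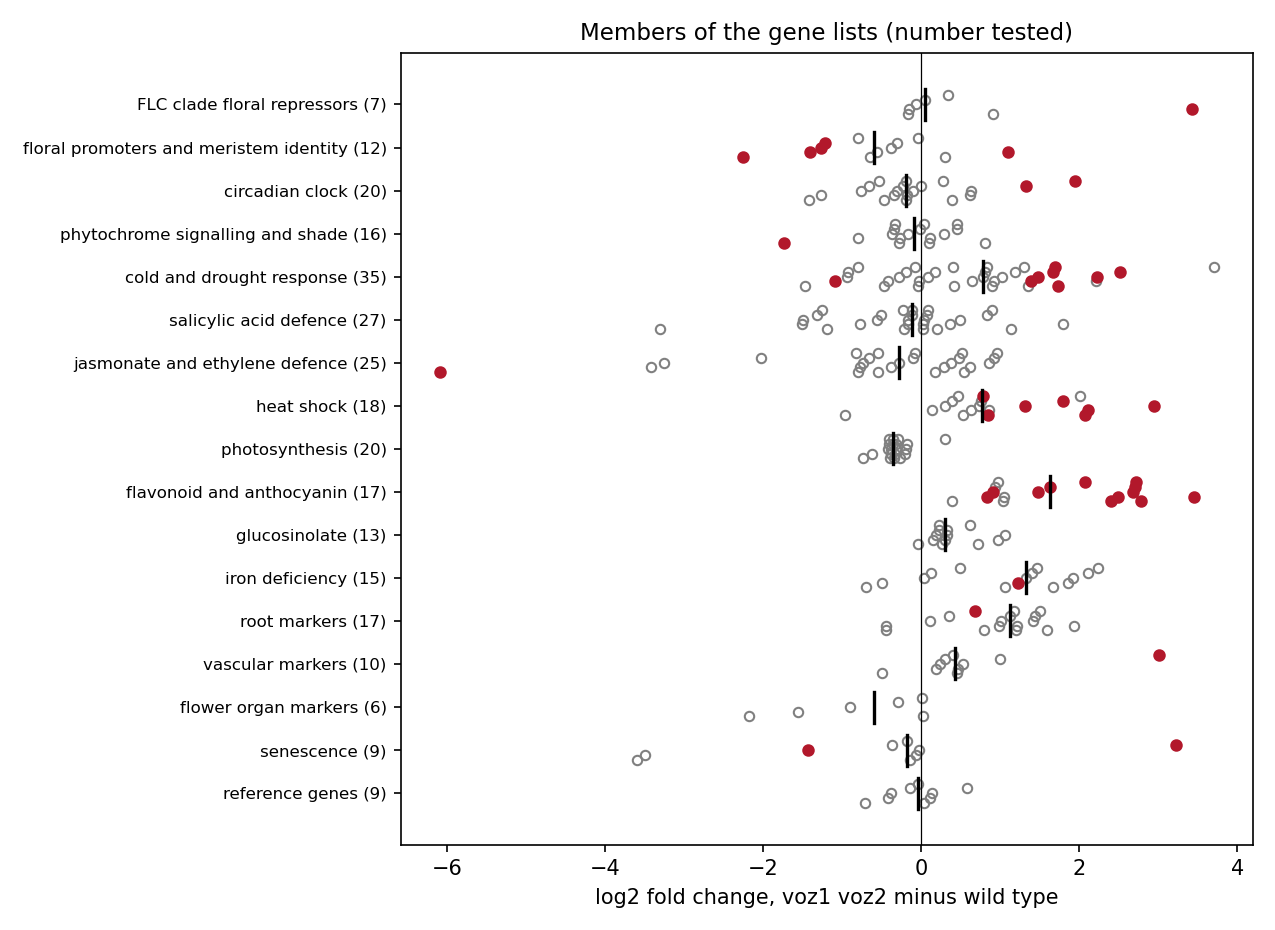
Log2 fold change (voz1 voz2 minus wild type, horizontal axis) of each tested member of the gene lists, 1 list per row with the number tested. Filled points passed the limma threshold over all genes, open points did not, vertical bars are list medians, and the flavonoid and anthocyanin row has all 17 members above 0.

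Heat shock genes were higher as a list. Among them 7 of 18 rose (13 rose and 1 fell adjusted over the list alone) and 17 had values above 0, with a median of 0.77. The chloroplast small heat shock protein gene HSP21 rose by 2.95 (SE 0.26, adjusted p = 0.0017), from -6.59 ± 0.19 to -3.64 ± 0.54 (SD, n = 4 each). The transcription factor gene DREB2C rose by 2.12, HSP17.6A by 2.07 and HSP70 by 1.32. HSP70 missed the threshold without wild type replicate 4 or mutant replicate 1 or 3, at an adjusted p of 0.050 to 0.059. The count of 7 dropped to 3 without wild type replicate 4 and to 4 without wild type replicate 1 or any 1 mutant array, and was 10 with slide and 11 with replicate as a block (1 lower with the latter), 0 with normexp and 1 in the values as deposited. HSP21 and HSP17.6A were well above background on 3 and 2 of the 4 wild type arrays, and with normexp HSP21, HSP17.6A and DREB2C had 0.83, 0.30 and 0.88 with no call. The camera adjusted p was 1.13e-08, and adjusted p = 0.146 with an estimated correlation, and the medians were 0.62 on slide 1 and 0.98 on slide 2.

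Cold and drought response genes differed in both directions, mostly upward. Of 35 genes 7 rose and 1 fell (12 and 2 adjusted over the list alone), with a median of 0.78. ERD7 rose by 2.52 (SE 0.23, adjusted p = 0.0019), the cold-response regulator CBF1 by 2.22 (SE 0.31, adjusted p = 0.0091), RD29A by 1.74 and DREB2B by 1.70. CBF1 was well above background on 2 of the 4 wild type arrays, and with normexp CBF1 and DREB2B had 0.25 and 0.75 with no call. GOLS1, a galactinol synthase gene named after its value was seen, had -1.09 (SE 0.23, adjusted p = 0.039), a call lost without any array but wild type replicate 2 and mutant replicate 1 (0.065 to 0.106), and with median scaling, normexp, no filter or the values as deposited (0.061 to 0.218). The count of 7 higher was 11 with slide and 13 with replicate as a block, 13 without wild type replicate 2 and 4 without mutant replicate 3, 3 with normexp and 0 in the values as deposited. The camera adjusted p was 0.0018, and adjusted p = 0.471 with an estimated correlation. The medians were 0.73 on slide 1 and 0.45 on slide 2, and 0.52 without wild type replicate 3 and 0.51 without mutant replicate 2.

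Genes that promote flowering were lower as a group. Of 12 tested, 4 fell and 1 rose (5 and 1 adjusted over the list alone), with a median of -0.60 (camera adjusted p = 0.0042, and adjusted p = 0.146 with an estimated correlation). The floral integrator SOC1 fell by 1.40 (SE 0.17, adjusted p = 0.0059), from 2.87 ± 0.25 to 1.46 ± 0.20 (SD, n = 4 each), a 2.64-fold change. SPL3 fell by 1.22 (SE 0.23), SPL4 by 1.27 (SE 0.25) and CAL by 2.25 (SE 0.45), with adjusted p of 0.028, 0.032 and 0.033. Leaving out 1 array ended the call of SPL3 for all but wild type replicate 2 and mutant replicate 1 (adjusted p 0.052 to 0.080) and that of SPL4 for all but wild type replicate 1 (0.050 to 0.088). The CAL call was lost without wild type replicate 1 or 4 or mutant replicate 1, 3 or 4 (0.060 to 0.090). The count of 4 lower was 5 with slide or replicate as a block, 2 without wild type replicate 1 or 3 or mutant replicate 1 or 2, 1 without wild type replicate 4 or mutant replicate 3 or 4, 1 with normexp or no filter, and 0 in the values as deposited. With normexp SPL3 and SPL4 had -1.04 and -0.80 with no call (adjusted p = 0.155 and 0.169), and CAL, well above background on 1 of the 4 mutant arrays, had -0.44. CO, named after its value was seen, had 1.09 (SE 0.22, adjusted p = 0.034), a call lost without any array but wild type replicate 4 (0.052 to 0.098), and with quantile or median scaling, normexp, no filter or the values as deposited (0.060 to 0.936). FT, the mobile flowering signal, had -0.80 (SE 0.37, 95% interval -1.64 to 0.048, adjusted p = 0.236). The list median was -0.50 on slide 1, where the call was lost (adjusted p = 0.068), and -0.85 on slide 2. LFY, AP1 and TSF were too dim to be tested.

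Of the 7 floral repressors of the FLC clade list, which also holds SVP from outside that clade, 1 rose, also adjusted over the list alone. MAF5 was higher by 3.43 (SE 0.78, adjusted p = 0.048), from -6.84 ± 1.52 to -3.41 ± 0.98 (SD, n = 4 each). Its call was lost at an adjusted p of 0.075 to 0.121 without any 1 of 6 arrays, the exceptions being wild type replicates 1 and 2, and with quantile scaling, eBayes robust, no filter, normexp (where it had 0.94) or the values as deposited (0.050 to 0.443). FLC itself had 0.047 (SE 0.45, 95% interval -0.99 to 1.08, adjusted p = 0.964), FLM -0.16, SVP -0.16, MAF2 0.34 and MAF3 -0.068, none past the threshold. The values of FLC and MAF2 were above 0 on slide 1 (0.49 and 0.95) and below 0 on slide 2 (-0.40 and -0.26), and that of FLC was also below 0 under quantile and median scaling, normexp and the deposited table. MAF3 was at 0.036 on slide 1. Without 1 array the sign also turned for FLC (wild type replicates 1, 2 and 3 and mutant replicate 4, to -0.22 at the lowest), MAF2 (wild type replicate 3, -0.47) and MAF3 (wild type replicates 2 and 4 and mutant replicate 1, to 0.13 at the highest). MAF4 had 0.91 (SE 0.66, adjusted p = 0.441), and passed with slide (adjusted p = 0.017) or replicate number (0.025) as a block. The list as a whole did not pass (median 0.047, and -0.17 on slide 2, camera adjusted p = 0.528).

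**Figure D2:**
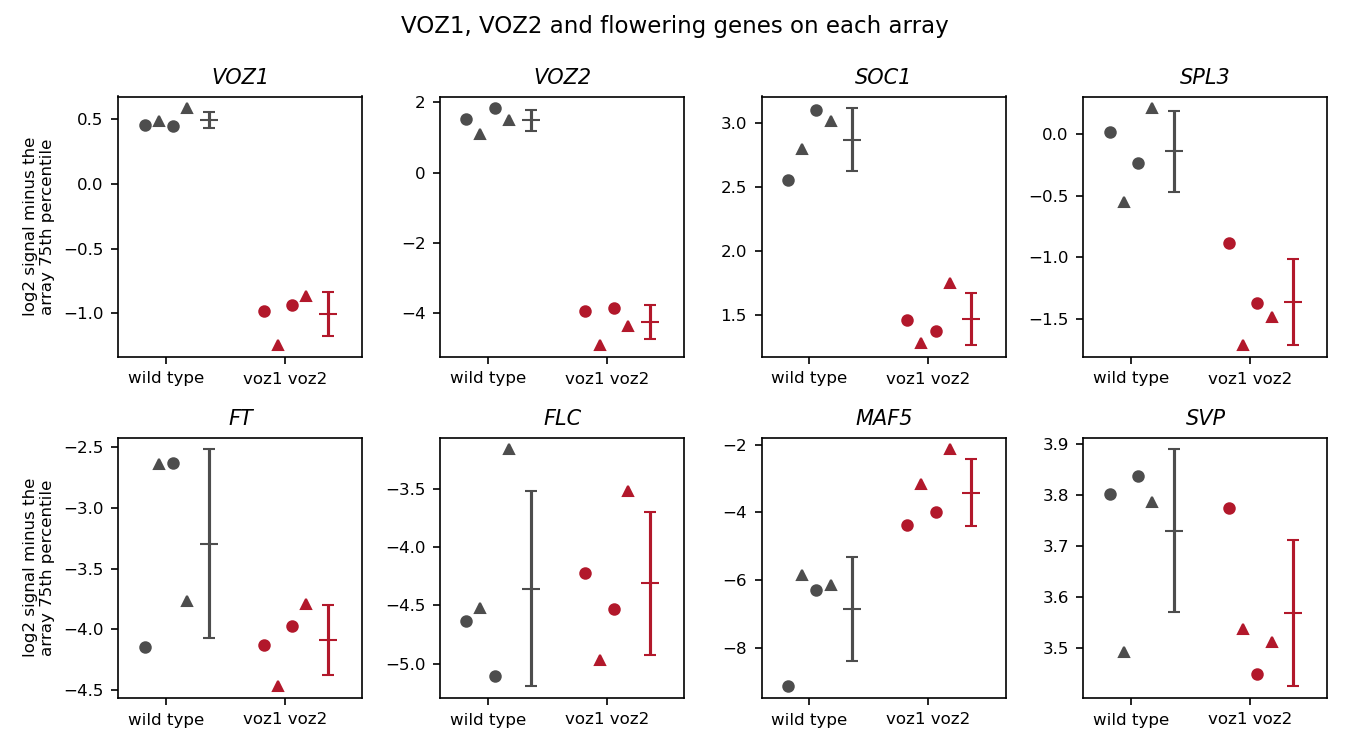
Level of VOZ1, VOZ2 and 6 flowering genes on each array, as log2 signal minus the array's 75th percentile (vertical axis, its range set per panel), with the mean and SD of the 4 arrays beside them. Circles are slide 1 and triangles slide 2, and SOC1 lies near 2.87 in wild type and 1.46 in voz1 voz2 while FLC overlaps between genotypes.

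The 10 rises taken by the rule were well above background on at least 1 array of each genotype. By estimated value they were led by the nicotianamine synthase gene NAS2, by 5.71 (SE 0.48, adjusted p = 0.0014, 52.4-fold), AT2G17660 by 4.93, SRO3 by 4.57 and DXPS1 by 4.44. AT5G09570, AT1G52120, AT1G51090, AT3G05950, AT3G03240 and AT5G39330 rose by 3.73 to 4.33. MYB21, a MYB factor known from stamen development, was not well above background in wild type and at least 26.8-fold higher in the mutant (adjusted p = 5.6e-05). On the same terms AT5G48510 was at least 14.3-fold and AT4G12735 at least 7.68-fold higher. In all, 29 genes past the threshold were higher with no wild type array well above background, and 7 were lower with no such mutant array. Among the 10 falls taken on the rule's same terms, the largest estimate was that of the plant defensin gene PDF1.2a at -6.09 (SE 0.98, adjusted p = 0.016), ahead of VOZ2. Next came AT4G25580 at -5.23, AT3G19550 at -5.04, AT1G26390 at -5.02, AT2G32870 at -4.53 and AT3G12730 at -4.45, then AT4G01600, AT1G67865 and the auxin carrier gene PIN5 at -4.29, -4.19 and -4.08. The sulfate transporter gene SULTR1;3 was at least 8.10-fold, AT4G01390 at least 11.5-fold and the calcium sensor gene CBL5 at least 5.50-fold lower. Sizes and ranks against a dim genotype are uncertain. The folds given as at least a value rest on each array's lowest signal well above background and leave out sampling error. They are therefore not lower limits under other background handling, and normexp gave a smaller size for each of these genes. SRO3 and AT3G03240 were well above background on 1 of the 4 wild type arrays and AT5G39330 on 2, and had 1.14, 0.61 and 0.85 with normexp. AT1G26390 and PIN5 were so on 1 of the 4 mutant arrays and AT1G67865 on 2, with -1.38, -0.75 and -1.10. Normexp, which adds an offset of 50, gave 0.61 to 3.61 for the 10 rises, -4.88 to -0.75 for the 10 falls with VOZ2 among them, 0.69 to 1.45 for MYB21, AT5G48510 and AT4G12735, and -0.82 to -0.56 for SULTR1;3, AT4G01390 and CBL5. Of the 52 named genes past the threshold, 38 passed without any single array and none changed sign under any alternative. Of the 52, 37 missed it with normexp and 28 in the values as deposited. The trend, robust and block fits could not turn a sign, as they leave the fold change of a gene with no missing value unchanged. Among the genes of this paragraph, single arrays ended the calls of AT1G51090 (wild type replicate 1 or any mutant array, adjusted p 0.052 to 0.072), AT3G05950 (all but wild type replicate 2, 0.058 to 0.092) and PDF1.2a (mutant replicate 3, 0.051). The same held for AT4G25580 (all but wild type replicate 1 and mutant replicate 4, 0.055 to 0.101) and AT1G67865 (all but wild type replicate 3, 0.065 to 0.108).

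The iron deficiency and root marker lists passed the list test upward, with 1 single call in each. Of 15 iron genes 1 rose (5 rose and 1 fell adjusted over the list alone), with a median of 1.33 (camera adjusted p = 0.0071, and adjusted p = 0.565 with an estimated correlation). NAS4 rose by 1.23 (SE 0.25, adjusted p = 0.033), a call lost at an adjusted p of 0.059 to 0.087 without any array but wild type replicates 2 and 3. The root ferric reductase gene FRO2 had 2.11 (SE 0.58, adjusted p = 0.076, and 0.048 with slide and 0.043 with replicate as a block). The iron transporter gene IRT1 had 2.24 (SE 0.69, adjusted p = 0.103), and its other probe 1.39. BTS had -0.70 (adjusted p = 0.068, and 0.025 with slide and 0.042 with replicate as a block). The medians were 1.15 on slide 1 and 1.59 on slide 2. Of 17 root markers 1 rose, WOX5 of the quiescent centre by 0.69 (SE 0.15, adjusted p = 0.045), a call lost whichever of the 8 arrays was left out (adjusted p 0.066 to 0.126). The root marker median was 1.12 (camera adjusted p = 0.0018, and adjusted p = 0.572 with an estimated correlation). It was 1.17 on slide 1 and 0.99996 on slide 2, where the call was lost (adjusted p = 0.055), and 0.61 without wild type replicate 4, whose mean over these genes was the lowest of the 8 arrays at -3.71. RSL4, MYB36 and CASP2 had 1.93, 0.98 and 1.01 with no call, and 1.17, 0.61 and 0.61 without wild type replicate 4. The mean of the root markers per array differed between genotypes by 0.92 (two-sided exact permutation p = 0.143), less than the spread allows to separate.

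Of 27 salicylic acid genes 0 passed the limma threshold, over all genes or adjusted over the list alone, and 4 had an unadjusted p under 0.05 (list median -0.12, and 0.21 without wild type replicate 1, camera adjusted p = 0.496). PR2 had -3.31 (SE 1.11, adjusted p = 0.124, and 0.024 with the replicate number as a block), DMR6 -0.56, FMO1 -1.19 and SARD1 1.80. Without wild type replicate 3, PR2 was at -4.31 (adjusted p = 0.043) and the list, with a median of -0.31, passed (camera adjusted p = 0.012), as it did with array weights (median -0.38, adjusted p = 0.045). Of 25 jasmonate and ethylene genes only PDF1.2a fell, also adjusted over the list alone (list median -0.28, 0.024 on slide 2, and without 1 array from -0.57 for wild type replicate 3 to -0.0089 for wild type replicate 1, camera adjusted p = 0.496). PDF1.2b and PDF1.2c had -3.42 (SE 0.99) and -3.25 (SE 0.94), with an adjusted p of 0.089 each, and 0.021 and 0.023 with the replicate number as a block, and JAZ6 had -0.66. Of 13 glucosinolate genes 0 passed in limma, over all genes or adjusted over the list alone, while 12 had values above 0 and 2 an unadjusted p under 0.05. The median was 0.30, but -0.035 in the values as deposited, and the camera adjusted p 0.022, with adjusted p = 0.572 with an estimated correlation. CYP79F2 had 0.97 (adjusted p = 0.077), MYB28 0.62 (0.102), MYB51 1.07 (0.213) and CYP79B2 0.71 (0.320). With slide as a block CYP79F2 and MYB28 passed (0.032 and 0.042), and with the replicate number CYP79F2 and MYB51 did (0.028 and 0.0498). The glucosinolate call was lost on slide 1 (median 0.24, against 0.37 on slide 2) and without wild type replicate 3 (median 0.12) or mutant replicate 2 (0.29), at an adjusted p of 0.070, 0.099 and 0.057.

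Among clock genes, LUX and ELF4 of the evening complex rose by 1.33 (SE 0.15, adjusted p = 0.0043) and 1.95 (SE 0.29, adjusted p = 0.011), 2 of 20 tested (2 higher and 6 lower adjusted over the list alone, and 4 lower with slide and 3 with replicate as a block), and the list did not pass (median -0.20, and without 1 array from -0.31 for wild type replicate 1 to -0.071 for wild type replicate 4, camera adjusted p = 0.495). RVE7 had -0.76 and RVE4 -0.54 with no call, except that both passed with the replicate number as a block (adjusted p = 0.038 and 0.034), and RVE4 with slide as a block (0.044) and without wild type replicate 2 (0.047). Of 16 phytochrome and shade genes PAR1, which restrains shade responses, fell by 1.74 (SE 0.39, adjusted p = 0.046), a call lost without any array but wild type replicate 2 (adjusted p 0.066 to 0.120). Adjusted over the list alone 2 of these genes fell. The locus number of PAR1, AT2G42870, is near that of VOZ2, AT2G42400. Whether the fall of PAR1 comes from a segment linked to the VOZ2 insertion was not tested for this gene. PHYA had -0.80, PIL1 0.81 and FHL 0.46. With the replicate number as a block PHYA and PIL1 passed (adjusted p = 0.035 and 0.0499), and PIL1 with slide as a block (0.044). The list median was -0.087, and above 0 with array weights (0.055) and without wild type replicate 4 (0.037) (camera adjusted p = 0.728). Among 9 senescence genes, the NAC factor NAP fell by 1.43 (SE 0.20, adjusted p = 0.0093) and SAG29 rose by 3.22 (SE 0.65, adjusted p = 0.034), the latter lost without any array but wild type replicates 2 and 3 (adjusted p 0.075 to 0.088). The dark-induced genes SEN1 and ASN1 had -3.59 (SE 0.99, adjusted p = 0.077) and -3.50 (SE 0.99, adjusted p = 0.082). Both passed with the replicate number as a block (adjusted p = 0.034 and 0.033) and without mutant replicate 4 (-4.67 and -4.56, adjusted p = 0.0059 and 0.0076), and SEN1 with slide as a block (0.038). Adjusted over the list alone 1 senescence gene rose and 3 fell. The list median was -0.18 (camera adjusted p = 0.171), with -0.57 without wild type replicate 3 and -0.077 without wild type replicate 4, and the list passed without mutant replicate 4 (median -0.41, adjusted p = 0.0057) and on slide 1 (0.034).

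Photosynthesis genes had a median of -0.35 (-0.19 without wild type replicate 4), with 0 of 20 past the threshold in limma, also adjusted over the list alone, 1 with an unadjusted p under 0.05 and 1 value above 0 (camera adjusted p = 0.084). The smallest p was that of PSBO2, which had no estimate on slide 1 because of missing values. It had -0.67 on slide 2 and -0.81 to -0.67 without 1 array. LHCB5 had -0.42 (SE 0.21), LHCA2 -0.36 and PSAF -0.38. This list passed on slide 1 (adjusted p = 0.014), with outlier spots kept (0.0051), with normexp (0.022), in the deposited table (0.029), and without wild type replicate 1 (0.020), wild type replicate 2 (0.039) or mutant replicate 4 (0.019). The 6 flower organ markers had a median of -0.60 with 0 genes past the threshold in limma, 2 with an unadjusted p under 0.05 and 1 lower adjusted over the list alone (camera adjusted p = 0.142). Their smallest p was that of SEP2 at -1.56 (SE 0.43, adjusted p = 0.077, and 0.046 with slide as a block), which passed without mutant replicate 2 (-1.99, adjusted p = 0.023), and AG had -0.90, PI -2.18 and SEP1 -0.29. Of 11 seed storage genes only EM6 was bright enough to be tested (-0.50, SE 0.24, adjusted p = 0.263). Of the 9 reference genes 0 passed in limma, 1 had an unadjusted p under 0.05, and 1 fell adjusted over the list alone (median -0.044, and 0.017 without wild type replicate 1, camera adjusted p = 0.412). Their values ran from -0.71 for ACT8 (SE 0.18, adjusted p = 0.059, and 0.035 with slide and 0.039 with replicate as a block, 0.029 with quantile scaling and 0.046 with eBayes trend) to 0.58 for GAPC1, with ACT2 at -0.43 and UBQ10 at -0.38.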

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

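All 8 results here are single arrays far from the other 3 of their genotype, among 193 groups of 4 values of named genes. Chance alone would pick out about 1 in 20 groups, more than the number found. Levels are log2 signals minus the array's 75th percentile.

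In voz1 voz2 replicate 3, AT1G51090 was at -2.01 against -3.21 to -3.15 on the other mutant arrays, and CASP2 at -0.84 against -1.51 to -1.44. In replicate 2, AT3G19550 was at -7.75 against -6.29 to -6.16. In replicate 4, PIN5 was at -9.92 against -7.87 to -7.68 and HSP21 at -4.44 against -3.45 to -3.29. In wild type replicate 1, MAF5 was at -9.11 against -6.28 to -5.85 and PI at -0.74 against 1.39 to 1.80. In wild type replicate 2, SVP was at 3.49 against 3.79 to 3.84. No biological or technical explanation of these single values was tested.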

How the results depend on the processing

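Each slide alone was chosen after seeing the data. The signal over background limits dim genes, and 4 arrays of each genotype limit the rest. The cause of a change below was not tested unless it is stated.

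The 1091 genes past the threshold (668 higher, 423 lower, 761 of 2-fold or more) ranged from 1019 to 1584 under quantile scaling, the all-array filter, mean and single probes, trend, robust, array weights and kept outlier spots. Array weights gave 707 lower and added the calls of PDF1.2b, PDF1.2c, CYP79F2, FRO2 and SWEET11. Median scaling gave 715 (402 higher), and 671 of the 1091 kept their call. Normexp gave 94 (75 higher, 19 lower, 86 of 2-fold or more). It left the arrays' lower quartiles at 6.05 to 8.17. The deposited table gave 70 (30, 40 and 70), and holds no array scaling. Without a filter MAF5, SPL3, SPL4, CAL, PAR1, NAS4, WOX5, SAG29, AT3G05950, AT4G25580 and AT1G67865 missed the threshold (adjusted p 0.059 to 0.103), as did PAR1, NAS4 and WOX5 with median scaling, WOX5 with eBayes trend, CAL with quantile scaling and AT4G25580 with array weights. No filter gave 514 (325, 189 and 485) among 36907 tested, and a threshold of 0.01 gave 226 (161, 65 and 219). The replicate block gave 3314 (1657, 1657 and 1310) and kept 1078 of the 1091 calls. The slide block gave 3955 (1999, 1956 and 1267) and kept all of them. Slide 1 alone and slide 2 alone gave 0 in every count, with fewer arrays. Without 1 array the counts were 387 to 1506 in all, 261 to 891 higher, 115 to 615 lower and 369 to 1109 of 2-fold or more. These fits had no slide block, with the genotypes unequal between slides.

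VOZ1 kept its fall everywhere, past the threshold except in the deposited table (-1.84) and on slide 1 (-1.41) and slide 2 (-1.59) alone. VOZ2 missed it only on slide 1 (-5.56) and slide 2 (-5.93). Of 17 lists tested 8 passed, 6 to 10 under other settings, but 0 with an estimated correlation and 3 with fry. Those 3 were flavonoid and anthocyanin (fry adjusted p = 6.5e-04), heat shock (0.0027) and floral promoters (0.015). The others that passed with camera missed it with fry. These were cold and drought (fry adjusted p = 0.062), iron deficiency (0.121), vascular (0.121), glucosinolate (0.172) and root markers (0.221). The replicate block changed no list call. It ended the call of no named gene, and the calls it added stand in the report.

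Of the 1091 genes 1 turned sign, a probe without a locus with normexp (1.05 to -0.16). Among the named genes and lists the signs below turned. FLC was at -0.025 with quantile scaling, -0.069 with median scaling, -0.47 with normexp, -0.29 in the deposited table and -0.40 on slide 2, and -0.22 to 0.44 without 1 array. MAF2 was at -0.26 on slide 2 and -0.47 to 0.74 without 1 array, and MAF3 at 0.036 on slide 1 and -0.26 to 0.13. The median of the FLC clade list was -0.025 with quantile scaling, -0.069 with median scaling, -0.066 with normexp, -0.29 in the deposited table, -0.010 with the all-array filter, -0.068 with single probes and -0.17 on slide 2, and -0.15 to 0.44 without 1 array. The jasmonate and ethylene median was 0.024 on slide 2, and the phytochrome median 0.055 with array weights and -0.15 to 0.037 without 1 array. Without 1 array the salicylic acid median was -0.31 to 0.21 and the reference gene median -0.091 to 0.017. Glucosinolate, the 1 list here that passed in the report's fit, was at -0.035 in the deposited table, where the median of all genes was -0.37.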

Other observations

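The test of the hour of harvest was chosen after the clock genes had been seen, and so were, after the list medians, the tests of the sugar and abundant root lists as means per array and all permutations within slides.

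Outside the lists of the report, genes that sugar is known to repress or induce were examined, as lists chosen after other genes' values were seen. All 14 sugar-repressed genes had fold changes below 0 with a median of -1.27, and 2 were past the threshold, the trehalose phosphate synthase gene TPS11 (-1.62, SE 0.31, adjusted p = 0.028) and AKINBETA1 (-1.28, SE 0.29, adjusted p = 0.046). All 5 sugar-induced genes had fold changes above 0 with a median of 1.72, and 3 were past the threshold, GPT2 at 2.85 (SE 0.55), TPS5 at 1.72 (SE 0.23) and APL3 at 1.25 (SE 0.23). Leaving out 1 array ended the calls of TPS11 and AKINBETA1 (all but wild type replicate 2 and mutant replicate 4, adjusted p 0.054 to 0.119), GPT2 (wild type replicate 4 or any mutant array, 0.067 to 0.081) and APL3 (all but wild type replicate 2, 0.055 to 0.075), but not that of TPS5. The calls of TPS11, AKINBETA1, GPT2 and APL3 were also lost with normexp (0.062 to 0.122), with no filter (0.054 to 0.087) and in the values as deposited, that of AKINBETA1 with median scaling (0.063), and that of TPS5 in the values as deposited (0.356). Among probes named by a genome position, 99 of 2281 passed the threshold, 39 higher and 60 lower in the mutant.

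SEN1 and ASN1 had lower values in the mutant while anthocyanin genes rose. A higher sugar status of the mutant seedlings may account for this, since the bootstrap 95% intervals over members were -1.62 to -0.67 for the sugar-repressed median of -1.27 and 0.29 to 2.85 for the sugar-induced median of 1.72. These intervals leave out the spread between arrays, and as means per array the lists differed by -1.45 (two-sided exact permutation p = 0.057) and 1.64 (p = 0.029, the smallest possible), with 0.056 for both, the smallest possible, when permuted within slides. Genes regulated together with SEN1 and ASN1 would have lower values under any shared cause. The sugar-repressed list therefore cannot favour sugar status over another shared cause, such as the hour of harvest. Harvest at another hour stays open, as evening minus morning clock genes differed between genotypes by 0.81 per array (95% interval 0.36 to 1.27, exact permutation p = 0.029, and 0.056 within slides, each the smallest possible). The interval holds 1, the shift above which another hour was to be read, a limit set after the clock genes had been seen. The evening set holds LUX and ELF4, both past the threshold. The difference therefore does not tell another hour from a change of LUX and ELF4 themselves. A direct effect of the VOZ genes on SEN1, ASN1 and the anthocyanin genes was not tested.

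The root marker and iron deficiency lists passed upward in the mutant with 1 call each, of 17 and of 15 genes, and as means per array differed by 0.92 and 1.05 (two-sided exact permutation p = 0.143 and 0.057, and within slides 0.222 and 0.056, the smallest possible), the iron mean being higher in the mutant in all 4 same-numbered pairs and the root mean in 3, with -0.18 in pair 2. Neither list passed with an estimated correlation (camera adjusted p = 0.572 for root markers and 0.565 for iron). Without wild type replicate 4 the root marker median was 0.61 in place of 1.12, the lowest without 1 array and above the limit of 0.56 set for a result that 1 array decides. A larger share of root RNA in the mutant samples may contribute. A separate list of 16 root genes, named abundant when it was made, met the limits set beforehand with 15 values above 0. Its median was 0.81 (bootstrap 95% interval over members 0.54 to 1.03), though 0 of 16 passed in limma and 4 had an unadjusted p under 0.05. The list's mean per array differed by 0.79 (exact permutation p = 0.143, and 0.222 within slides). Not all its members were bright in these seedlings. Those with a wild type level above 0, PYK10, PBP1, NRT1.5 and PHO1, had fold changes of -0.048, 0.64, 0.079 and 0.35. The dimmer members, down to a wild type level of -6.00 for MRN1, had 0.15 to 1.71. PYK10, an abundant root transcript at 4.74 in wild type and chosen after its value was seen, had -0.048 (SE 0.15), which an equal rise of every root transcript would not give. The other 15 of these 16 genes had values above 0. For the iron list, its mean minus that of the root markers differed by 0.13 per array (two-sided exact permutation p = 0.600, and 0.667 within slides), so a larger root share and a response of the iron genes cannot be told apart with 8 arrays.

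Genes past the threshold lay together, with 46 pairs of neighbouring loci past the threshold in the same direction, against a mean of 22.6 over 10000 shuffles of the gene order (permutation p = 0.0001, the smallest these can give). A neighbouring pair chosen after its values were seen is AT4G01380 at -2.60 (-0.39 with no call with normexp) and AT4G01390, at least 11.5-fold lower (-0.76 with no call with normexp). For segments linked to the VOZ1 and VOZ2 insertions, the share of genes past the threshold was compared. Of the 100 tested loci on each side of both genes 6% passed and 4.44% elsewhere (odds ratio 1.37, 95% interval 0.87 to 2.09, below the 3 set as the limit, Fisher's exact p = 0.141). How many of the 46 pairs lay near the 2 genes was not counted. The share therefore does not decide whether linked segments add to the pairs. By locus name AT4G01380 and AT4G01390 lie on another chromosome than VOZ1 and VOZ2. Tandem copies read by the same probe were not tested.

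Other splits of the 8 arrays into 4 and 4 were counted. Of 35 splits, 2 gave as many as 1091 genes, the real one and the split by slide with 4128, so by this count alone chance is not excluded at 1 in 20. The split by slide points to a structure of the samples, and with slide as a block the genotypes differed in 3955 genes. The highest of the remaining splits gave 1 gene. Among the 8 splits that part all 4 same-numbered pairs, the other 7 gave 0 genes. In every split but the real one, the genotype difference lies within the groups and widens their spread, which favours low counts. For the gene lists, 5 of the 35 splits gave as many as the real 8, the highest being 12, so chance is not excluded for the number of lists past the threshold.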
